A study of Drosophila pseudoobscura and Drosophila ananassae and Drosophila yakuba with 13 samples.

How the data were processed

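RNA from testes and ovaries of D. pseudoobscura, D. ananassae and D. yakuba was sequenced as single reads of 50 bases. Per the labels' protocols, the flies were virgin adults aged 6 to 10 days, gonads were freed of their ducts before extraction, polyadenylated RNA was selected, and libraries were made with random priming by a TruSeq kit from Illumina, with no statement on strand. The labels give 13 samples in 6 groups, each group being a species and a tissue, with 2 testis and 3 ovary libraries for D. pseudoobscura, 2 and 2 for D. ananassae and 1 and 3 for D. yakuba. D. yakuba was not analysed here. All libraries of a species have their growth temperature in common, 20 °C for D. pseudoobscura and 25 °C for the others, so species and temperature cannot be told apart. Libraries were run on one of a pair of sequencer models, and the labels do not say which library ran on which, so sequencer batches could not be checked.

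Per the submitters' processing notes, the authors used Bowtie2 2.1.0, HTSeq 0.5.4p3, Cufflinks 2.1.0, Cuffdiff 2.1.0 and edgeR, whose version, the genome builds, the annotation, the count filter and the normalization are not given in the sources used here. The files used are 1 table per species of the authors' own edgeR comparison of testis and ovary, with no values per library. Per the file headers, the deposited values are a log2 fold change, a log2 average expression, a likelihood-ratio statistic, a p-value and a false discovery rate for each gene. The likelihood-ratio statistic is a score in the authors' deposited table with 1 degree of freedom: the deposited p-value equalled its chi-square tail within 0.49%, and the deposited false discovery rate, called adjusted p here, equalled the Benjamini-Hochberg value over the genes of the table within 0.82%. Because depth per library is unknown, no confidence interval on counts was computed.

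The deposited log2 average expression is headed as log CPM, but its linear values summed to 6.69e+06 and 8.09e+06 times the total of 1000000 that CPM has, in the authors' deposited tables of D. ananassae and D. pseudoobscura. It was therefore rescaled within each table to a sum of 1000000, and every minimum on average expression refers to the rescaled value. Fold changes were taken as deposited by the authors. Their direction is not in the file headers. Positive values were read as higher in testis from the order of tissues in the table's title, and checked against genes of known gonad expression.

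Genes were called testis-biased or ovary-biased at the authors' adjusted p under 0.05. Before the data were examined, 18 gene lists were fixed with D. melanogaster symbols, covering testis regulators, meiosis, sperm chromatin and tail, chorion, vitelline membrane, yolk, maternal patterning, oogenesis, the piRNA pathway, replication, accessory gland, muscle, fat body, gut, somatic gonad, ribosomal proteins and dosage compensation. Because the tables name few genes, 9 lists had no measured member under their listed symbols in either species. PCNA, a member of the replication list, appears in the D. ananassae table under another symbol, mus209, and was not counted there. In D. pseudoobscura the copies exu1 and exu2 of exu, a maternal patterning member, and troponin genes of the muscle list likewise carry other symbols and were not counted. Members were matched by listed symbol only. Further members of any list, in either direction, may be present under other symbols, which were not searched for systematically. Lists with at least 3 measured members were tested two-sided with cameraPR of limma 3.58.1 in R 4.3.3, on the signed normal score of the p-value with a preset correlation of 0.01, adjusted over the lists. The rule for named genes, also fixed before the data were examined, took up to 4 members of each list by smallest adjusted p, the 5 genes per direction with the largest fold among named genes with a log2 average expression of at least 5, the 5 named genes of highest average expression, and 2 identifiers per direction. In D. ananassae 2 named genes qualified towards testis. Members of families and other genes outside this rule were chosen after their values were seen.

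Shared symbols were compared between species by Spearman and Pearson correlation with 100000 permutations, and the overlap of calls by a two-sided Fisher's exact test. Family shares were compared by the same exact test and with 10000 random lists matched on average expression. The error behind the p-values was derived, after the data were examined, from genes with a rescaled log2 average expression of at least 6 and an absolute log2 fold change of 0.2 to 1, as the squared fold in natural log units divided by the likelihood-ratio statistic. Computations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.

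The arithmetic of the error's derivation was checked on simulated data. All simulated genes had 1 dispersion, and the simulated statistic was computed with that same value, so its recovery was largely fixed in advance. Whether the authors' deposited tables rest on a shared error was not tested in this way. For D. ananassae (11576 genes) the recovered dispersion was 1.04 times the one put in, and for D. pseudoobscura (11946 genes) 1.01 times. Of genes changed by 1 on the log2 scale in simulated D. ananassae data, 60.0% were called, 90.0% of those changed by 2 and 100% of those changed by 4 or 8. In D. pseudoobscura the shares were 0%, 26.0%, 96.0% and 100%. Only 200 genes were changed in each simulation, so the adjusted threshold was stricter there than in the authors' deposited tables. These shares therefore do not show how often such changes were called in the real data. In D. pseudoobscura 333 of 346 genes with a deposited log2 fold change of 2 to 3, and 963 of 990 at -3 to -2, were called. Of 200 simulated lists of 4 genes shifted by 3 standard deviations among 11946 genes of D. pseudoobscura, cameraPR recovered 100%, and it called 7.0% of lists without a shift at a p under 0.05.

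The alternatives were stricter thresholds of 0.01 and 0.001, minimum folds of 2 and 4, Bonferroni adjustment, minimum rescaled log2 averages of 1 and 3, centring on the median gene, a preset correlation of 0.05, ranks, and matched random lists. A share of testis-biased genes on the X chromosome was planned and not computed. The reference table used here is of the D. pseudoobscura assembly UCI_Dpse_MV25, none of the gene identifiers of either table matched it (0 of 11576 and 0 of 11946), and symbols matched for 41 and 143 genes, so chromosomes and coordinates are not given.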

Results

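Gene expression in testis and ovary was measured by RNA sequencing in Drosophila, with the aim, as the title of the series states it, of finding genes whose expression is biased towards 1 sex in the gonad. The 13 libraries came from dissected gonads of virgin adults aged 6 to 10 days, from which the attached ducts had been removed. D. pseudoobscura, grown at 20 °C, was represented by 2 testis and 3 ovary libraries, and D. ananassae, grown at 25 °C, by 2 libraries of each tissue. D. yakuba, with 1 testis and 3 ovary libraries, was not analysed here. The values below come from the authors' deposited table for each species, which holds 1 fold change, 1 average expression and 1 test per gene. These tables carry no column per library, so the depth of each library is unknown and no spread between replicates could be computed for a gene. A positive log2 fold change is read here as higher expression in testis. The header does not state this direction: it was taken from the order in which the table's title names the tissues and from genes of known gonad expression, so those genes are not independent evidence of direction.

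In D. ananassae, the testis-biased genes included Pof, which encodes a chromosome-binding protein, and TrxT, a thioredoxin of the testis. Their log2 fold changes in the authors' deposited table were 7.70 and 4.56. Ovary-biased genes with the largest folds among named genes with a log2 average expression of at least 5 were mus209 at -8.66, the maltase gene Mal-A5 at -8.45, msl-1 at -6.86, CBP at -6.70 and hb at -6.48, again from the authors' deposited table. The gene mus209 encodes PCNA, the sliding clamp of DNA replication. Of the 11576 genes in the authors' deposited table, 3664 (31.7%) were testis-biased and 6226 (53.8%) were ovary-biased at an adjusted p under 0.05. The remaining 1686 genes (14.6%) were not called. Ovary-biased genes were the more numerous and testis-biased genes had the larger folds, with a median log2 fold change of 5.72 (interquartile range 2.13 to 8.32) against -2.69 (-4.10 to -1.60) in the authors' deposited table. Among testis-biased genes 53.7% exceeded 5 on the log2 scale, and among ovary-biased genes 15.0% lay below -5. Among genes known here only by identifier, with the same minimum of expression, the most extreme folds were those of GF17233 at 16.1 and GF15813 at 15.6 towards testis and GF20786 at -15.0 and GF15930 at -14.4 towards ovary in the authors' deposited table. Folds of this size depend on how the fit treats a tissue with almost no reads, and they are not bounds on the difference. The median gene stood at -0.93, so a fold is also read against that shift. The normalization behind the folds is not given, so whether the shift and the larger number of ovary-biased genes are partly technical is not known. With a minimum of 4-fold the ovary-biased genes numbered 4092.

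Of the 31 genes of the maternal patterning list 2 were measured in D. ananassae, and both were ovary-biased, hb, a transcription factor of the early embryo, and nos, a translational repressor that patterns the posterior. In the authors' deposited table nos stood at -3.56. The oogenesis list had 1 measured member of 30, plu, which acts in the early embryonic cell cycles and stood at -4.15 in the authors' deposited table. For the piRNA pathway the member measured was rhi, which marks piRNA source loci in the germline, at -2.25 in the authors' deposited table. The ribosomal protein gene RpS18, at -4.18, and msl-1, a component of the dosage compensation complex, were ovary-biased as well in the authors' deposited table. In the list of somatic gonad genes the Wnt ligand gene wg was testis-biased, at 2.85 with an adjusted p of 0.0084 in the authors' edgeR likelihood-ratio test and the authors' deposited table. No list reached the 3 measured members set for a test in this species. All of these 7 members were called, so adjustment over the list alone could not remove a call and is no further support. None of the 7 changed sign when folds were centred on the median gene, while under Bonferroni adjustment the call of wg was lost. The general thioredoxin gene Trx-2, among the 5 most abundant named genes, was ovary-biased at -4.59 in the authors' deposited table. Named genes were few, 59 of the 11576, and the lists of testis-specific regulators, sperm chromatin, sperm tail, chorion, vitelline membrane, yolk, replication, muscle, accessory gland, fat body and gut genes had no measured member under their listed symbols.

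In D. pseudoobscura, among named genes with a log2 average expression of at least 5, those with the largest testis bias were exu2 at 12.8, the odorant-binding protein genes Obp44a at 10.6 and Obp99a at 9.34, amd at 7.76 and the sex determination pathway gene fru at 7.51 in the authors' deposited table. With the same minimum of expression, the largest ovary bias among named genes was that of dhd, a thioredoxin of the female germline, at -17.3, followed by HP1Da, of the heterochromatin protein 1 family, at -13.8, Mal-A5 at -12.7, the transcription factor gene cbt at -11.5 and Trx-2 at -11.0 in the authors' deposited table. Testis-biased genes numbered 3540 (29.6%) and ovary-biased genes 5269 (44.1%) of the 11946 genes in the authors' deposited table, and 3137 (26.3%) were not called. The median log2 fold change was 8.67 (3.81 to 12.8) for testis-biased and -4.23 (-7.02 to -2.50) for ovary-biased genes in the authors' deposited table. The shares beyond 5 on the log2 scale were 68.7% of testis-biased and 41.5% of ovary-biased genes. Identifiers at the extremes, with that minimum, were GA16698 at 20.0 and GA26684 at 19.8 towards testis, and GA15558 at -20.3 and GA22302 at -19.9 towards ovary, in the authors' deposited table. The median gene stood at -0.85, and whether that shift is partly technical is likewise not known. Under Bonferroni adjustment the ovary-biased genes numbered 3279.

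**Figure D1:**
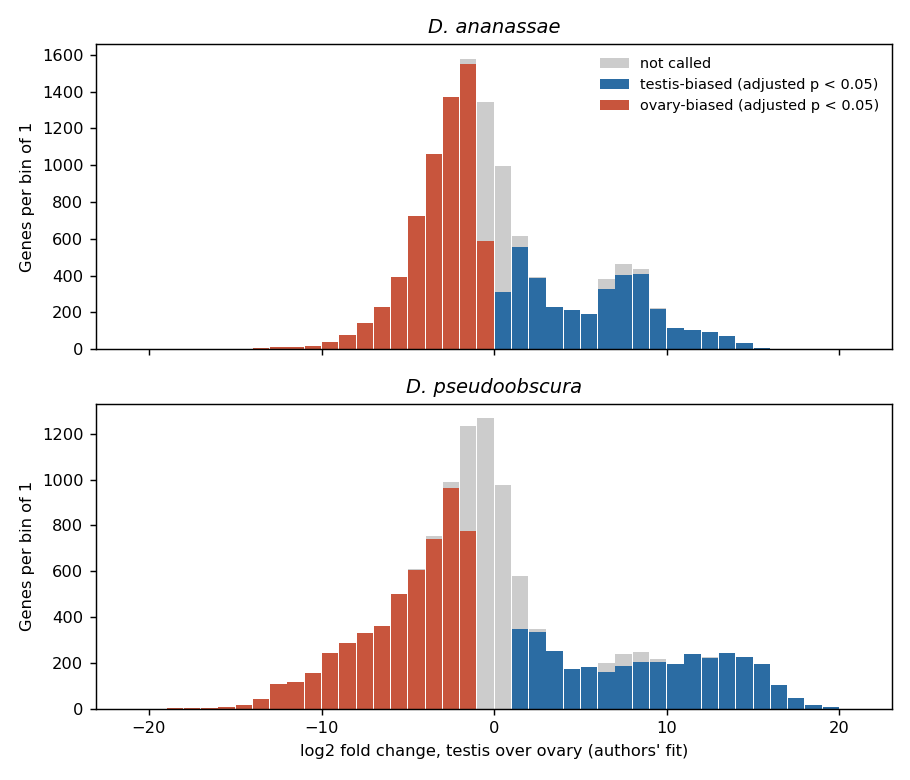
Number of genes per bin of 1 of the log2 fold change of testis over ovary in the authors' deposited tables, for D. ananassae (top) and D. pseudoobscura (bottom); coloured parts are genes with an adjusted p under 0.05 and grey parts are genes not called. Ovary-biased genes outnumber testis-biased genes in both species (6226 against 3664, and 5269 against 3540), and the median fold of testis-biased genes is the larger in size (5.72 against -2.69, and 8.67 against -4.23).

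The 4 maternal patterning genes of D. pseudoobscura measured under their listed symbols were ovary-biased. They were bcd, the anterior determinant, at -9.82, Tl, the receptor of the dorsoventral pathway, at -9.21, swa, needed to localise bcd mRNA, at -3.48, and hb at -2.46 in the authors' deposited table. The 3 muscle genes measured under their listed symbols were ovary-biased too. These were the tropomyosin genes Tm2 at -9.21 and Tm1 at -3.0 and the myosin light chain gene Mlc1 at -7.35 in the authors' deposited table. Troponin genes are on the muscle list under other symbols, were not counted and are given below. As lists compared with the other genes, maternal patterning and muscle each had an adjusted p of 0.0556 in limma's cameraPR, above the threshold. With ranks in place of scores each had an adjusted p of 0.0338, and list medians lay at the 0.53 and 0.78 percentiles of random lists matched on expression. A correlation between members could not be estimated without values per library. The maternal patterning list also names exu, whose copies carry other symbols and were not counted. Both copies went the other way, with exu1 at 2.41 and exu2 at 12.8, testis-biased in the authors' deposited table. The lists were not tested with such genes added. The accessory gland genes measured under their listed symbols, Acp26Aa at 5.56 and Acp53Ea at 9.05, were testis-biased in the authors' deposited table. Both had low average expression, -0.32 and -0.35 on the rescaled log2 scale. Members of that list under other symbols were not searched for, so the direction of the whole list is not known. Among somatic gonad genes, the ecdysone receptor gene EcR was ovary-biased at -9.88 and chinmo, which maintains male identity in somatic stem cells of the testis, was testis-biased at 6.83 in the authors' deposited table. The gut maltase gene Mal-A1 stood at -3.97, RpL32 at -2.45 and msl-1 at -1.59, called as ovary-biased in the authors' deposited table. The 14 list members counted here were all called, so adjustment over the list alone could not remove a call and is no further support. None of the 14 changed sign when folds were centred on the median gene. Under Bonferroni adjustment the calls of hb, Tm1, Acp53Ea, RpL32 and msl-1 were lost, and msl-1, at -0.74 after centring, was also lost with a minimum of 2-fold. Lists of testis-specific regulators, sperm chromatin, sperm tail, chorion, vitelline membrane, yolk, oogenesis, piRNA pathway, replication and fat body genes had no measured member under their listed symbols.

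Beside RpL32, the most abundant named genes of D. pseudoobscura were those of a chaperone, a cyclophilin and a pair of mitochondrial proteins. The mitochondrial ADP/ATP carrier gene sesB at -5.49, the cyclophilin gene Cyp1 at -3.96 and ATPsyn-beta, a subunit of ATP synthase, at -2.79 were ovary-biased in the authors' deposited table. The chaperone gene Hsp83, the most abundant named gene, was not called, with a log2 fold change of -0.45 and an adjusted p of 0.509 in the authors' edgeR likelihood-ratio test and the authors' deposited table. Its value became 0.40 when folds were centred on the median gene. Under Bonferroni adjustment the call of ATPsyn-beta was lost.

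Families of genes recognised by their symbols were chosen after their values were seen, and shares of calls were compared with the rest of each table by a two-sided Fisher's exact test, adjusted over 38 tests. Small nucleolar RNA (snoRNA) genes, whose products guide modification of ribosomal RNA, were ovary-biased in 73 of 76 cases in D. ananassae (96.1% against 53.5% of other genes, adjusted p = 5.64e-15 by Fisher's exact test on the authors' deposited table). In D. pseudoobscura 26 of 27 were ovary-biased (96.3% against 44.0%, adjusted p = 8.17e-08 by Fisher's exact test on the authors' deposited table). Median snoRNA folds were -6.75 and -9.26 in the authors' deposited tables, and -5.82 and -8.41 relative to the median gene. Spliceosomal snRNA genes were ovary-biased in 21 of 21 and 12 of 12 cases in the authors' deposited tables, with medians of -3.86 and -5.03. Among 10000 random lists matched on average expression these medians lay at the 0.36 percentile in D. ananassae and at the 15.8 percentile in D. pseudoobscura, so in the second species the snRNA median was within the range of matched lists. The 46 copies of 5.8S ribosomal RNA listed for D. ananassae were ovary-biased as well, with a median of -5.54 in the authors' deposited table. Transfer RNA genes, few in both species, were ovary-biased in 3 of 5 cases in D. ananassae and in 0 of 3 in D. pseudoobscura in the authors' deposited tables, where none of the 3 was called. Copies of snRNA and 5.8S ribosomal RNA are near-identical and can share reads, so their values are uncertain one by one and are not independent, and these p-values are then too small. Whether snoRNA genes share host genes could not be checked without coordinates, so their p-values may be too small as well.

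Among protein-coding families of D. pseudoobscura, 5 of 5 accessory gland peptide genes were testis-biased (adjusted p = 0.0087 by Fisher's exact test on the authors' deposited table). Beyond the pair from the fixed list these were Acp53C14a at 9.12, Acp53C14b at 8.31 and Acp53C14c at 7.87 in the authors' deposited table, named after their values were seen. Their rescaled log2 averages were low as well, -0.21, -0.76 and -0.96, a range in which large folds towards testis were often not called. The copies can share reads and are then not independent, so the p-value of Fisher's exact test may be too small. The troponin genes TpnCIb at -11.3, TpnCIa at -10.6, TpnT at -9.26 and TpnI at -7.84, of striated muscle, were ovary-biased in the authors' deposited table. TpnCIIIa was testis-biased at 3.66, and TpnCIIIb, at -1.54, was not called in the authors' deposited table. Of the heterochromatin protein 1 family HP1Da, HP1B at -3.74, HP1C at -2.84 and HP1A at -1.36 were ovary-biased and HP1Kcd was testis-biased at 5.29 in the authors' deposited table. The thioredoxin genes split by tissue, with TrxT testis-biased at 5.89 and dhd and Trx-2 ovary-biased in the authors' deposited table. The exu copies were both testis-biased, exu1 at 2.41 and exu2 at 12.8 in the authors' deposited table. None of these named genes changed sign after centring on the median gene, and under Bonferroni adjustment the calls of Acp53C14b, Acp53C14c, TpnCIIIa, HP1A, HP1C, HP1Kcd and exu1 were lost. HP1A, at -0.51 after centring, was also lost with a minimum of 2-fold. The ovary-biased share of the 6 troponin genes did not pass the threshold in Fisher's exact test (adjusted p = 0.544). The 5 heterochromatin protein 1 and 3 thioredoxin genes are too few for that test to pass for ovary bias, whatever their calls. The median folds of these families lay at the 0.09, 11.6 and 0.12 percentiles of random lists matched on average expression, with members on both sides in each family.

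**Figure D2:**
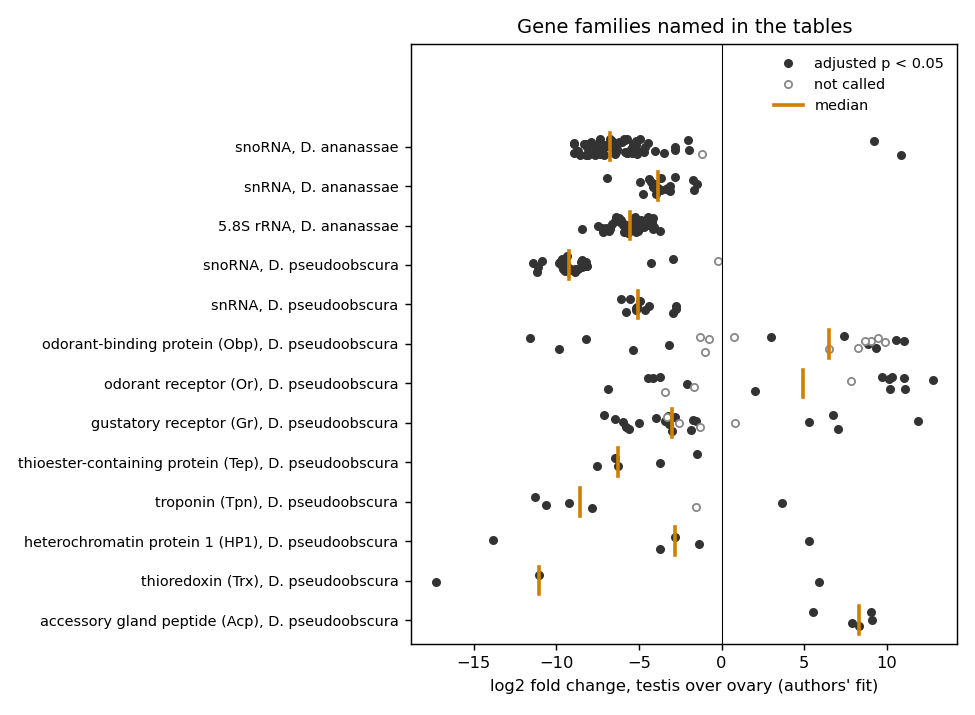
Log2 fold change of testis over ovary in the authors' deposited tables for members of gene families, 1 point per gene, with filled points at an adjusted p under 0.05, open points for genes not called and an orange bar at the family median; vertical scatter within a family only separates the points. The snoRNA genes lie on the ovary side with medians of -6.75 in D. ananassae and -9.26 in D. pseudoobscura, and the accessory gland peptide genes on the testis side with a median of 8.31.

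Both tables listed 36 symbols in common, which allowed the same contrast to be compared between species. Higher expression in testis was called in both species for TrxT and the metallothionein gene MtnA, at 1.30 and 2.97, out of 4 testis-biased genes in each of the authors' deposited tables, where independent lists would share 0.444 (two-sided Fisher's exact p = 0.0527). Ovary bias was called in both species for 27 genes, out of 29 in D. ananassae and 28 in D. pseudoobscura in the authors' deposited tables, where independent lists would share 22.6 (two-sided Fisher's exact p = 9.49e-05). They included Mal-A5, cbt, at -6.11 and -11.5, hb, msl-1 and Trx-2, and the centromeric histone gene cid, at -5.53 in D. ananassae and -1.39 in D. pseudoobscura in the authors' deposited tables. Across these genes, which are not independent replicates, fold changes correlated with a Spearman's rho of 0.607 (permutation p = 0.00013, adjusted p = 0.00038 over 8 correlations) and a Pearson's r of 0.694 (permutation p = 1e-05, the smallest that 100000 permutations can give). Without the 2 genes farthest from the median in D. ananassae Pearson's r was 0.617 (permutation p = 0.00019). Of the 36 genes 12 were snRNA copies, and without them rho was 0.697 over 24 genes (permutation p = 0.00031). Without the snRNA copies 15 ovary-biased genes were shared against 11.3 for independent lists (two-sided Fisher's exact p = 0.00132), and 2 testis-biased genes against 0.667 (p = 0.115 by the same exact test). Of 30 genes called in both species 1 had opposite directions. It was the circadian clock gene per, testis-biased at 1.00 in D. ananassae and ovary-biased at -7.59 in D. pseudoobscura in the authors' deposited tables. Under Bonferroni adjustment the calls of per in D. ananassae and of hb, msl-1 and cid in D. pseudoobscura were lost, and those of msl-1 and cid in D. pseudoobscura also after centring with a minimum of 2-fold. The tables hold separate comparisons whose normalization is not given in the sources used here, and the difference between species was not tested.

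**Figure D3:**
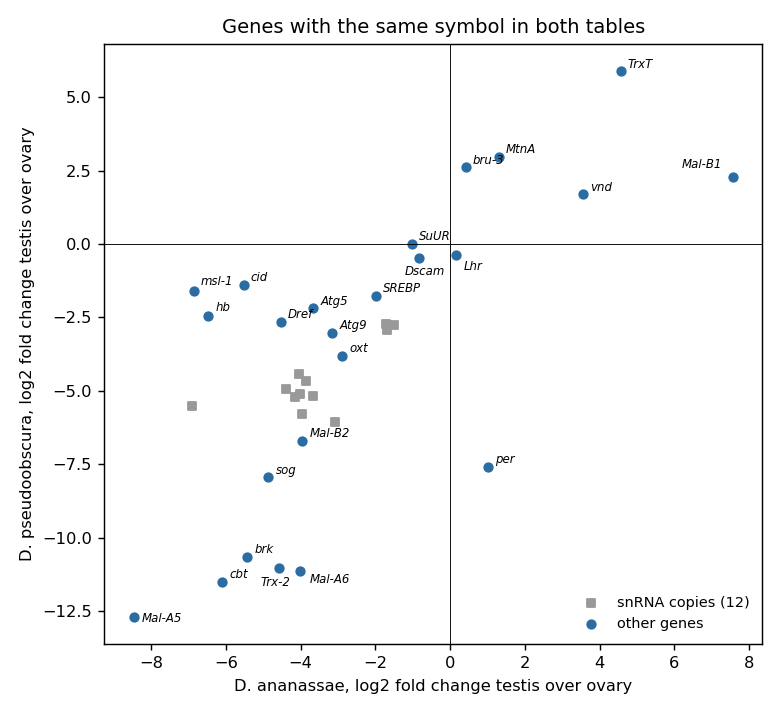
Log2 fold change of testis over ovary in D. ananassae (horizontal) and D. pseudoobscura (vertical) for the 36 genes with the same symbol in both of the authors' deposited tables, with 12 snRNA copies as grey squares and the other genes as labelled blue points. Most genes lie in the quadrant of higher ovary expression in both species (Spearman's rho 0.607), and per, called in both species, lies on the testis side in D. ananassae and the ovary side in D. pseudoobscura.

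The precision of a fold change could be read only from the tables themselves. For abundant genes with small folds, the ratio of the squared fold to the likelihood-ratio statistic was almost constant within each of the authors' deposited tables, corresponding to a standard error of 0.257 on the log2 scale in D. ananassae and 0.606 in D. pseudoobscura. The smallest fold called among abundant genes was accordingly 0.52 in D. ananassae and 1.24 in D. pseudoobscura in the authors' deposited tables. For these genes, 552 in D. ananassae and 587 in D. pseudoobscura, the p-values therefore rest on an error that the genes share and do not show how far each gene's own replicates agreed. For genes of low expression or with large folds the ratio was not examined, and the error behind their p-values is not known here. How the shared error was estimated is not given in the sources used here. Nothing states that libraries came from separate pools of flies, so any spread between libraries that this error reflects can be technical.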

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

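Counts without small RNA classes, with the other species' shared error or without low genes far up in testis, and correlations without snRNA copies or the 2 farthest genes, were chosen after the data were seen; the other alternatives were planned. In D. ananassae the testis-biased count ranged from 2766 to 3664, within 1.5 times the reported value, and the ovary-biased count fell to 4092 at a minimum of 4-fold, by construction, with other values from 4203 to 6229. In D. pseudoobscura the testis-biased count ranged from 2506 to 4290, and the ovary-biased count fell to 3279 under Bonferroni, which adjusts more strictly, with other values from 3708 to 6372. Centred on the median with at least 2-fold, the ovary share of calls was 53.4% in D. ananassae (63.0% as reported) and 56.9% in D. pseudoobscura (59.8%). The p-values used there still tested the fold before centring, so no testis-biased gene could be gained. Testis-biased counts stayed at 3664 and 3540. These shares therefore do not show whether ovary-biased genes would remain the more numerous in a test of centred folds. The maternal patterning and muscle lists of D. pseudoobscura, with members counted by listed symbol only, each reached an adjusted p of 0.0338 with ranks, and percentiles of 0.53 and 0.78 among matched random lists, against 0.0556 as reported and 0.0652 with a preset correlation of 0.05. The cause was not tested. Cross-species rho stayed between 0.529 and 0.697, and Pearson's r between 0.617 and 0.694.
For 75 named gene and species pairs, 257 of 279 repeated values kept their direction and call, 17 calls were lost under Bonferroni and 4 after centring with at least 2-fold (msl-1, cid and HP1A in D. pseudoobscura, SuUR in D. ananassae), and uncalled Hsp83 changed sign after centring, from -0.45 to 0.40. Centring moved every fold of a table towards testis by the same amount, so it could not remove a testis-biased call. Many adjusted p-values from the authors' likelihood-ratio test lay far below the threshold, where a minimum on average expression could hardly change the call. The 257 kept values are therefore no measure of robustness. No paired analysis was possible because the tables used hold no columns per library. DESeq2, no count filter, leaving out each library and a replicate block were not run for the same reason, and the X-linked share was not run because identifiers matched no chromosome. Depth per library is unknown, so its limits cannot be given.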

Other observations

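The tests weighed in this part were chosen after the values were seen. Chemosensory genes of D. pseudoobscura were found on both sides. Of 16 odorant receptor genes 8 were testis-biased and 5 ovary-biased, of 21 odorant-binding protein genes 6 and 5, and of 23 gustatory receptor genes 4 and 15, in the authors' deposited table. None of these shares passed the threshold after adjustment by Fisher's exact test (adjusted p for the testis-biased share = 0.206, 1.0 and 0.430, and for the ovary-biased share = 0.471, 0.184 and 0.154). Their median folds, 4.92, 6.53 and -2.98 in the authors' deposited table, lay at the 99.1, 99.9 and 16.3 percentiles of random lists matched on average expression, so the odorant receptor and odorant-binding protein medians lay far towards testis. These medians include genes with large folds that were not called. The odorant-binding protein median is the fold of Obp83a, which had an adjusted p of 0.777 in the authors' edgeR likelihood-ratio test. The percentiles therefore rest in part on uncalled folds and do not show a testis bias of these families. The 5 thioester-containing protein genes, of innate immunity, were ovary-biased, with Tep2 at -7.53 in the authors' deposited table. With 5 of 5 the share is at its maximum and the adjusted p was 0.0576 by Fisher's exact test, so a family of this size could not pass for ovary bias, and their median lay at the 0.82 percentile of matched random lists. The amylase genes numbered 5 in D. ananassae, of which 3 were testis-biased and 0 ovary-biased, and 3 in D. pseudoobscura, of which 3 were ovary-biased, in the authors' deposited tables. Amylase copies can share reads, and the difference between species was not tested. Amylase medians lay at the 77.2 and 32.5 percentiles of matched random lists in D. ananassae and D. pseudoobscura. Of maltase genes 4 of 5 were ovary-biased in each species in the authors' deposited tables, against 53.8% and 44.1% of other genes, with medians at the 4.77 and 2.23 percentiles. By Fisher's exact test the adjusted p was 0.518 and 0.336, in families again too small to pass.

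Ovary bias of snoRNA genes appeared in both species, in 96.1% and 96.3% of genes. Low average expression, which could let noise set the direction, is argued against: of 10000 random lists matched on average expression the highest share was 68.4% in D. ananassae and 85.2% in D. pseudoobscura. A shift of the whole table towards ovary is argued against as well, since the median after centring was -5.82 and -8.41. Reads from introns of host genes, unequal capture of RNA without a poly-A tail and a difference between the tissues stay open, because the tables give no coordinates and no library values. No biological explanation was tested.

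A group of genes had a log2 fold change above 5 towards testis without a call, 144 in D. ananassae and 147 in D. pseudoobscura, and no gene below -5 was uncalled in either of the authors' deposited tables. Obp83a was one of them, at 6.53 with an adjusted p of 0.777 in the authors' edgeR likelihood-ratio test and the authors' deposited table. In the same range of average expression there were 322 and 474 ovary-higher genes below -5, and all 322 and all 474 were called. An average in that range thus did not by itself prevent a call on the ovary side. Average expression within the range was not compared between the 2 sides. Testis-higher genes above 5 in that range were called in 157 of 301 cases (52.2%) in D. ananassae and in 119 of 266 (44.7%) in D. pseudoobscura. In pairs of a called and an uncalled gene among these, the called gene had the higher average expression in a share of 0.7615 and 0.859, so low average expression may contribute, and the values leave open whether it is the whole cause. A floor on the ovary side would make the fold rise 1 for 1 with average expression. It may account for the size of these folds in D. ananassae, where the slope was 1.19 with a residual SD of 0.073. The slope lay near the upper end of a range set after the values were seen. It concerns the size of the fold and does not show why these genes were not called. In D. pseudoobscura the slope was 1.43, outside the range of 0.8 to 1.2 set for that explanation, with a residual SD of 0.645, and the values leave it open. Reads in a single testis library could give such genes and stay untested without library values.

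The share of genes called was smaller in D. pseudoobscura, 73.7% against 85.4%. With the shared error of D. ananassae applied to its statistics 89.3% of D. pseudoobscura genes would be called, and with the errors exchanged the other way 67.2% of D. ananassae genes. That exchange extends an error measured on abundant genes to the whole table, so it was repeated over the 3311 and 3714 abundant genes of D. pseudoobscura and D. ananassae. There the share called moved from 71.1% to 88.6% in D. pseudoobscura, short of the 90.4% of D. ananassae, and from 90.4% to 75.3% in D. ananassae. A larger shared error may thus account for part of the difference, and the values leave open whether it accounts for the whole of it, and whether that error came from the flies, the dissection or the libraries.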
